A study of Mus musculus with 4 samples.

How the data were processed

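The data are droplet single-cell RNA sequencing libraries of sorted red fluorescent mouse cells: 1 of the atrioventricular canal at E9.5, 1 of the mitral valve at E16.5 and 2 of the mitral valve at P0. Per the labels, dissected tissue spent 5 or 10 min in a dissociation enzyme, serum at 10% stopped the digest and tomato-positive cells were sorted, and 3' libraries were read over 57 nt on a NextSeq 500. Per the labels, the deposited counts are UMI counts per gene and cell that the authors made with Cell Ranger 2.1.1 on genome build mm10; the values are whole numbers, and no normalization was applied. The counting settings, the counting strand and the rule by which cells were kept are not given in the sources used here. The deposited gene tables, other text values that name the genes, hold 27998 Ensembl gene identifiers with symbols in the order of the matrix. In the table of P0 replicate 1, 15 symbols had been turned into dates, so each symbol was taken by identifier as the other tables give it, and 121 identifiers that share a symbol with another were kept apart by identifier. Genome positions and transcript lengths come from the mouse GENCODE annotation of GRCm38.

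The matrices held 1206 cells at E9.5, 452 at E16.5, and 291 and 211 at P0. The barcode lists of E9.5 and E16.5 held all 737280 possible barcodes and those of the P0 libraries were exchanged, so cells were used by their column and barcodes were not used here. Because the matrices had already been reduced to cells, the planned rule for calling cells was replaced by taking every deposited cell. The lowest UMI totals were 5480, 493, 1719 and 1381 per cell. Cells with under 500 genes (0 at E9.5, 105 at E16.5, 2 and 27 at P0), with over 10% mitochondrially encoded UMIs (7, 65, 6 and 8, some under both) or scored as doublets by scrublet within their library (7, 6, 2 and 1) were left out. This kept 1192, 310, 281 and 176 cells, with a median of 2353.5 UMIs at E16.5 and 5155 and 4433 at P0. The tdTomato reporter is not in the gene table, so the sort could not be checked from the counts.

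Each library was clustered alone with scanpy 1.11.5 (Python 3.11.15, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) on 2000 variable genes, 20 principal components and 15 neighbours, with the Leiden method at resolution 1.0 and seed 0. No annotation of cells by the authors was used here, and clusters were named from 15 marker lists fixed with the design. A marker counted where its share of the cluster's UMIs was at least 2-fold that in the library's other cells, with 0.1 per 10000 UMIs added to both, and at least 10% of the cluster's cells had it. A cluster took the name with the largest share of its list counted if at least 3 markers counted, if the next unrelated name's share was at most 0.75 times as large, and if its 10 leading genes by fold did not hold more markers of another name. Leading genes were taken among those in at least 20% of the cluster's cells, with 0.5 per 10000 UMIs added. These thresholds, and the rule that a cluster with at least 4 endothelial and at least 4 interstitial markers is called mixed, were set after the clusters were seen. A stricter rule for ties was tried and dropped because it left the interstitial cluster of P0 replicate 1 without a name. Clusters left without a name held 20.4% of kept cells at E9.5, 18.1% at E16.5, and 27.4% and 16.5% at P0, and in 2 of these at P0, 16.7% and 16.5% of the cells, several interstitial markers were raised beside markers of other types. A rebuilt name can differ from the authors' own.

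Raw UMIs were summed per library and class, because cells are not replicates. The interstitial side held 102 cells with 2157234 UMIs at E9.5 (the mixed cluster), 76 with 167649 at E16.5, and 66 with 301082 and 44 with 191071 at P0. The endothelial side held 89 cells with 2173747 UMIs, 69 with 181246, 54 with 360677 and 53 with 292702. E16.5 or E9.5 was compared with P0 by edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling and the quasi-likelihood test, the 4 sums forming 3 groups, on genes reaching the CPM of 10 counts in the smallest library in at least 1 library. The fit has 1 residual degree of freedom, so the spread comes from the P0 libraries alone and the single E9.5 and E16.5 libraries were assumed to vary like them. The prior degrees of freedom were infinite in both fits, with a common coefficient of biological variation of 0.1096 (interstitial) and 0.168 (endothelial). A gene was called where the Benjamini-Hochberg adjusted p was under 0.05 and the single library lay on the same side of both P0 libraries. Fold changes of genes with 0 UMIs on a side are bounds against 3 UMIs over the group, and genes with 1 to 3 UMIs are given as a ratio with an exact conditional binomial interval. E16.5 and E9.5, with 1 library each, were compared without a test by the ratio of UMI shares. Both E16.5 and E9.5 were set against the same P0 libraries, so no overlap between these comparisons is given. Levels carry exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only.

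There were 19 gene lists, fixed with the design, the comparisons, the tests and the rule for naming genes before the data were examined, and 2 of their genes were not in the table. For each list the members passing in each direction were counted over all genes and adjusted over the list alone, and the median log2 fold was placed among 10000 random lists of the same size drawn from the same 10 bins of mean expression. No gene set test with an estimated correlation was run. Genes were named by rule: per comparison the 8 largest rises and 8 largest falls among called genes with at least 30 UMIs in the higher sum, leaving out ribosomal protein, mitochondrially encoded, haemoglobin and sex-specific genes and gene models without a name, then up to 2 called members per direction of each list, or its highest member where none was called. Some genes that this rule takes are not reported here. Across all deposited cells the P0 libraries correlated at r = 0.948 over 9418 genes, which are not independent, with a chi-square of 3.57 per degree of freedom.

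The alternatives were a minimum of 500 or 1000 UMIs per cell, no mitochondrial limit, at least 1000 genes per cell, no doublet removal, Leiden resolutions 0.5 and 2.0, 1 clustering of all libraries, cells thinned to 1000 UMIs (2 E16.5 cells were shallower), no low-count filter, DESeq2 size factors, library totals, DESeq2 1.42.0 with its Wald test, leaving out each P0 replicate, and for the untested comparisons 5 UMIs, a 1.5-fold limit and TMM-scaled totals. Added after seeing the data were fits without ribosomal protein genes, mitochondrially encoded genes and Malat1, fits without the E16.5 or the E9.5 library, a test of whether the E16.5 change differs between the classes, and levels in the cells of the named clusters with at least 1000 genes without clustering again. Each alternative on cells was clustered and named again, so its classes can hold other cells. The procedure was tested on simulated data with the depths and spread of these sums. edgeR recovered 21.1% of 2-fold and 66.3% of 4-fold changes in interstitial E16.5 against P0 and called 2 of 2781 unchanged genes. For interstitial E9.5 it recovered 43.6% and 86.3% (0 of 2825), for endothelial E16.5 18.8% and 60.5% (2 of 3399) and for endothelial E9.5 20.9% and 88.6% (1 of 3373). The size rule found 35.4% and 50% of 4-fold interstitial and endothelial changes and passed 0 of 7877 and 1 of 7879 unchanged genes. It was tested with counting error only, so these values say nothing of variation between libraries. Of 100 unchanged lists, 4 and 7 lay outside the middle 95% of random lists. Figures were drawn with matplotlib 3.10.9.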

Results

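Single-cell RNA sequencing followed the Tie2-Cre lineage of the mouse heart, the descendants of endothelial cells, through the making of the mitral valve. The parents carried Tie2-Cre and a tdTomato reporter that Cre switches on, and red fluorescent cells were sorted after microdissection from at least 60 embryos per stage. There were 3 groups: the atrioventricular canal at E9.5 (1 library), the mitral valve at E16.5 (1 library) and the mitral valve of newborns at P0 (2 libraries). The age field of the E16.5 sample holds a mistyped value, so E16.5 was taken from its title and the protocol. The E9.5 library held 1206 cells with 30819374 UMIs, a median of 24564.5 UMIs and 4617 genes per cell. The E16.5 library was shallow, with 452 cells, 1021188 UMIs, and a median of 1914.5 UMIs and 700.5 genes per cell. P0 replicate 1 held 291 cells with 1836768 UMIs (median 5029 per cell), and P0 replicate 2 held 211 cells with 1086623 UMIs (median 3934 per cell). Nothing in the labels shows that the P0 libraries came from separate litters, so p-values measure the spread between these samples, which may be technical, and intervals cover counting error only. E9.5 and E16.5 had no replicate, so stage and library coincide at both, and at E9.5 the dissected region differs as well.

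Interstitial-like cells, the matrix-making mesenchyme of the leaflet, and endothelial-like cells of the valve surface type were named in all 3 libraries from the mitral valve when each library was clustered alone. Of 310 kept E16.5 cells, 24.5% (exact Clopper-Pearson 95% interval 19.8 to 29.7) were interstitial-like, and the P0 replicates had 23.5% (18.7 to 28.9) and 25% (18.8 to 32.1). With all libraries clustered together these shares were 55.2%, 40.2% and 40.3%. Of the 171 E16.5 cells then named interstitial-like, 76 came from the interstitial-like cluster used here, 36 from the smooth muscle or pericyte-like cluster, 56 from clusters without a name and 3 from the endothelial-like cluster. When only cells with at least 1000 genes were kept and clustered again, 33 E16.5 cells took the interstitial name. Of these, 4 came from the interstitial-like cluster used here, 15 from the smooth muscle or pericyte-like cluster and 14 from clusters without a name. Values from these settings describe classes of other membership. Endothelial-like cells made up 22.3% (17.8 to 27.3) at E16.5 and 19.2% (14.8 to 24.3) and 30.1% (23.4 to 37.5) at P0. Clustered together, endothelial-like cells made up 21.6% at E16.5 and 15.9% at E9.5, but 0 of 281 and 0 of 176 cells at P0, where 32.7% and 36.9% of the cells stayed without a name. Of the 190 at E9.5, 101 came from the mixed cluster described below. A further endothelial group with capillary or coronary markers (Fabp4, Cd36, Gpihbp1) made 19% (14.8 to 23.9) at E16.5 and 26.3% (21.3 to 31.9) and 21.6% (15.8 to 28.4) at P0. At E9.5, 41.6% (38.8 to 44.5) of 1192 kept cells were cardiomyocyte-like and 20.4% (18.1 to 22.8) erythroid-like, while endothelial-like cells made up 7.47% (6.04 to 9.11). No E9.5 cluster met the interstitial name, so 0 of 1192 cells had it (limit 0.252% at 3 counts, counting error only). Cells took their cluster's name and 20.4% had none, so the interstitial-like share is not bounded. Unnamed E9.5 clusters 4 and 9 each had 4 interstitial markers raised, with 9 and 0 endothelial ones. Cluster 4 (102 cells, 8.56% of the library) was led by Tagln2, Hapln1, Pdlim3, Apoe and Eng. This mixed cluster is the interstitial side of the E9.5 comparisons. Cluster 9 (65 cells), led also by Prrx1, was not compared. Sorting and dissection decide what enters each library, so shares describe libraries and not tissue.

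**Figure D1:**
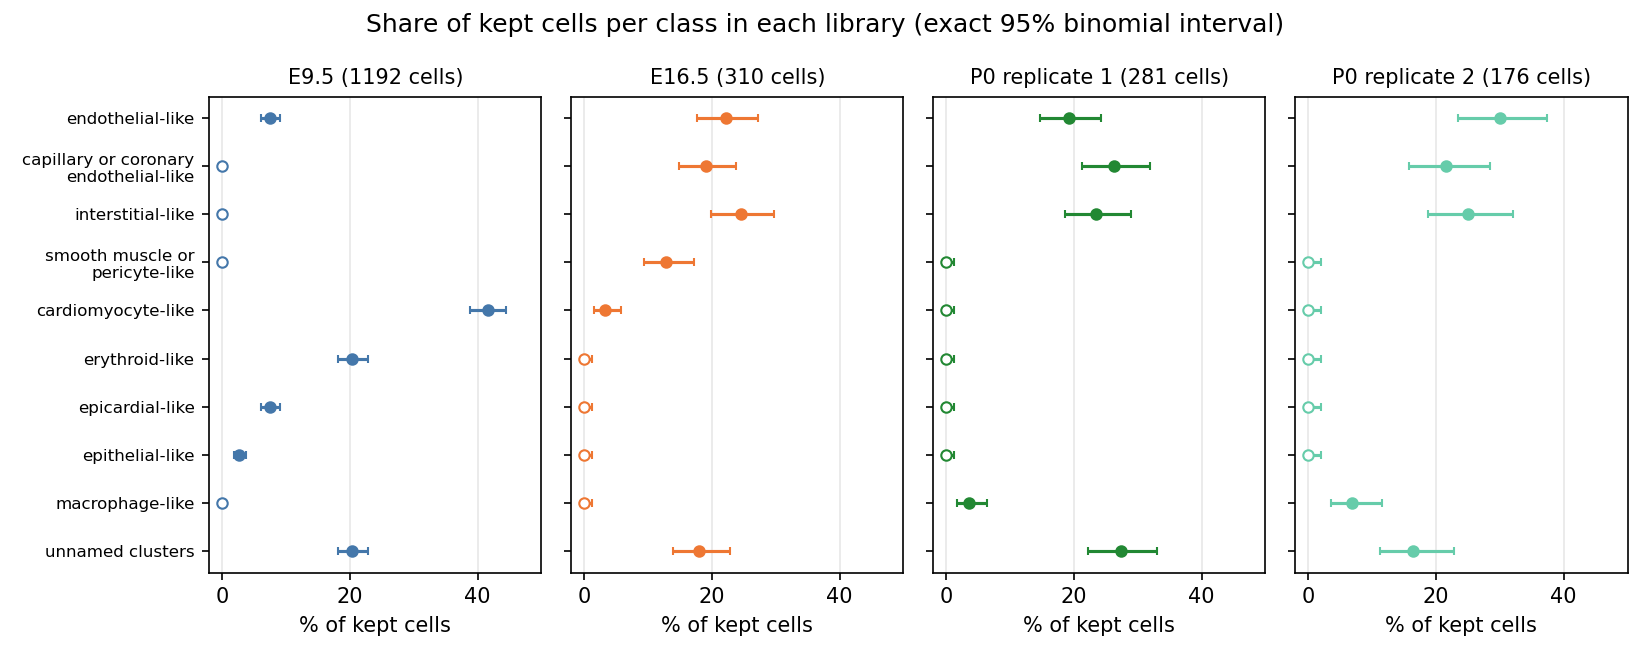
Share of kept cells (x axis, %) assigned to each class (y axis) in each of the 4 libraries, points with exact 95% binomial intervals and open points where no cell was assigned. Interstitial-like cells lie between 23.5% and 25% in the 3 mitral valve libraries, and cardiomyocyte-like cells reach 41.6% at E9.5.

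Broad RNA classes differed between the libraries. Malat1, a long nuclear non-coding RNA, stood at 6.70 UMIs per 10000 UMIs in the kept E16.5 cells and 21.1 in the E9.5 cells, against 344 and 332 in the P0 replicates. Cytosolic ribosomal protein genes took 3290 UMIs per 10000 at E16.5, 1548 at E9.5, and 2352 and 2387 at P0. Mitochondrially encoded genes took 446.6 at E16.5 against 326 and 281 at P0. Genes that respond to tissue dissociation, such as Fos and Junb, summed to 35.8 (95% Poisson interval 33.0 to 38.8) in E16.5 interstitial-like cells against 91.2 (87.9 to 94.7) and 99.8 (95.3 to 104) at P0. An E16.5 cluster without a name, 41 cells led by Thbs1, Ccl2 and Ddit3, stood apart from the interstitial-like one, whereas Thbs1 was among the genes that led the interstitial-like clusters at P0, so the class may split differently by stage. The dissociation list stood at 30.4 (27.0 to 34.1) in that cluster.

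**Figure D2:**
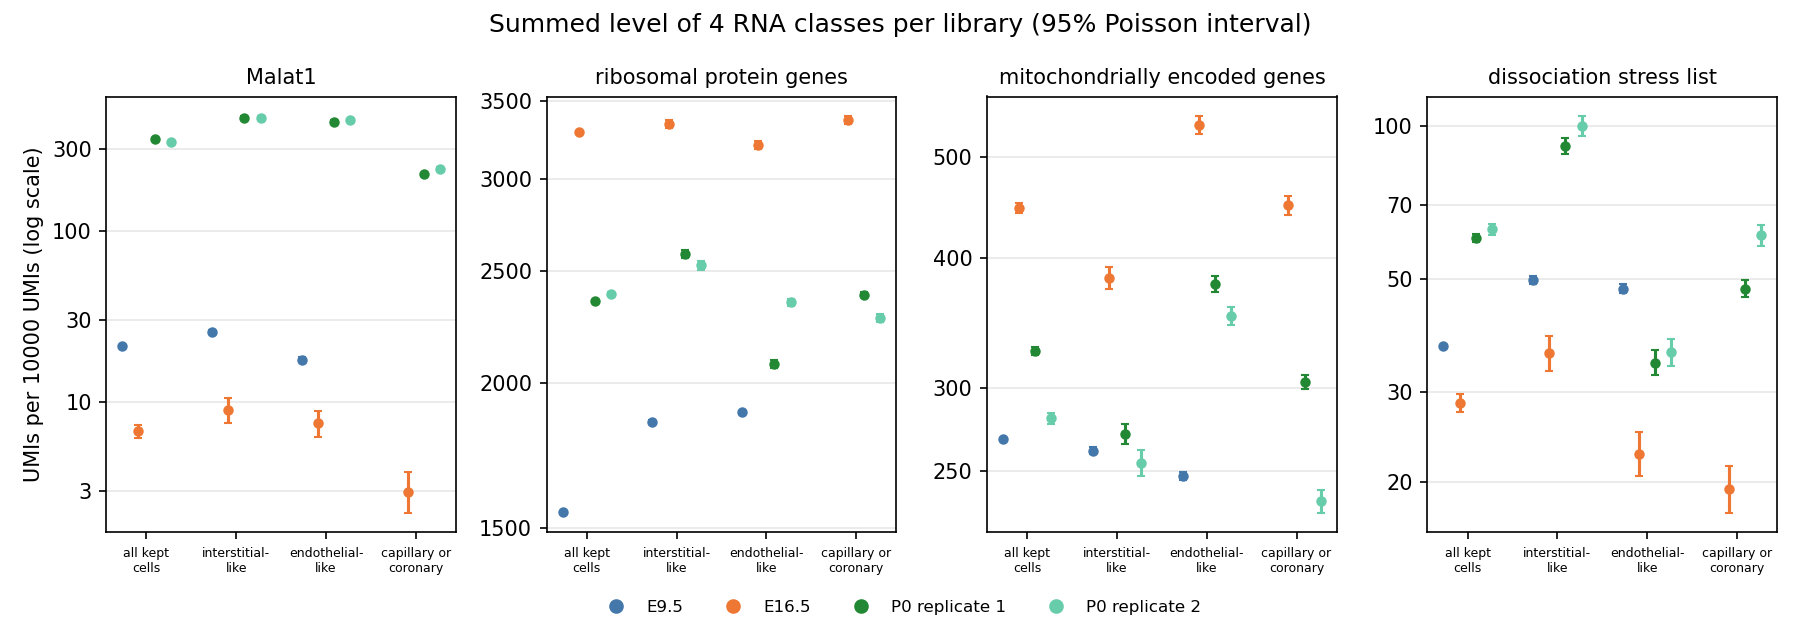
UMIs per 10000 UMIs (y axis, log scale) of Malat1, ribosomal protein genes, mitochondrially encoded genes and the dissociation stress list, by cell class (x axis) and library (colour), with 95% Poisson intervals. Malat1 is at 6.70 in the kept E16.5 cells and above 300 in both P0 libraries.

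The E16.5 and P0 interstitial-like cells were compared to ask how leaflet mesenchyme changes late in valve growth, within the series' stated interest in the fate and behaviour of mitral valve progenitors. Some collagen, elastic fibre and tendon-type genes were higher at E16.5 than at P0, and Hes1 and Notch2 of the Notch pathway were lower. Col5a1, a chain that starts fibrillar collagen assembly, stood at 4.59 UMIs per 10000 (95% Poisson interval 3.62 to 5.74) against 1.64 ± 0.544 (SD, n = 2) at P0. Scx, a tendon transcription factor, stood at 2.03 (1.40 to 2.83) against 0.356 ± 0.0598, and Loxl1, an elastin cross-linking enzyme that also led the E16.5 cluster against other E16.5 cells, at 6.74 (5.55 to 8.10) against 2.64 ± 0.401. Hes1, a transcriptional repressor induced by Notch, stood at 0.358 (0.131 to 0.779) against 3.09 ± 0.145.

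By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Col5a1 rose with a log2 fold of 1.85 (SE 0.31, adjusted p 5.3e-08) and Scx with 2.90 (SE 0.69, adjusted p 2.4e-04), the E16.5 library lying above both P0 libraries. By the same quasi-likelihood test with Benjamini-Hochberg adjustment Hes1 fell with a log2 fold of −2.69 (SE 0.52, adjusted p 3.0e-06), below both P0 libraries. Col5a1 is ENSMUSG00000026837 at chromosome 2, 27886425 to 28039514 (GRCm38/mm10, as all positions here). Loxl1 is ENSMUSG00000032334 at chromosome 9, 58287738 to 58313186, Scx is ENSMUSG00000034161 at chromosome 15, 76457452 to 76459458, and Hes1 is ENSMUSG00000022528 at chromosome 16, 30064384 to 30067796. In all, 582 genes rose and 450 fell of 3668 tested. Of 1021 of these calls 94.4% had the same sign in capillary or coronary endothelial-like cells, so most may not be particular to mesenchyme. With library totals in place of TMM scaling 374 rose and 867 fell, so the higher share of the calls went from 56.4% to 30.1% and the median log2 fold from −0.10 to −0.55, while no call changed sign.

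Among the matrix lists, 7 of 11 measured fibrillar and associated collagens rose and 4 did not pass, with 7 also when adjusted over the list alone, Col16a1 at 1.93 and Col6a3 at 1.02. The collagen list's median log2 fold of 0.81 lay at percentile 87.8 of random lists matched on expression; with library totals 2 rose and the median was 0.36. DESeq2 called 4. Of 13 elastic fibre genes 5 rose, with 5 also adjusted over the list alone (Loxl1 1.75, Fbln2 1.33), and 8 did not pass; the median of 0.66 lay at percentile 74.4, and library totals and DESeq2 left 3 each. Of 6 measured cartilage, tendon and bone genes 5 rose, with 5 also adjusted over the list alone, at percentile 98.2; with library totals 2 rose and the median went from 1.16 to 0.70, and DESeq2 called 1. Among them was Col2a1, the main cartilage collagen, with 19 UMIs against 0 at P0, at least 18.6-fold higher. Of 12 proteoglycan and hyaluronan genes 1 rose and 2 fell, or 2 and 4 adjusted over the list alone, and the median of −0.73 lay at percentile 1.56; with library totals 1 rose and 7 fell. Fmod, a small collagen-binding proteoglycan that also led the E16.5 cluster, rose (1.89, but −1.29 in the other class of cells with at least 1000 genes), whereas Lum, itself a marker used to name the class, fell (−1.69) and the syndecan Sdc1 fell (−1.59). Of 9 basement membrane genes 2 rose (Lama4 1.35, Hspg2 1.29), 1 of them adjusted over the list alone, and their median of 0.26 became −0.19 with library totals, where 0 passed.

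Among signalling and transcription lists, 2 of 4 Notch pathway genes fell (Hes1 and Notch2, −1.77), with 2 also adjusted over the list alone and a median of −1.76 at percentile 1.03. Of 10 EndMT transcription factors, the set that drives endothelial-to-mesenchymal transition, 3 rose and 1 fell, with the same counts adjusted over the list alone, and with library totals 1 rose and 3 fell. Snai1 rose (2.97, on 12 UMIs against 6), as did Twist1 (1.42), a class marker, while Zeb1 fell (−1.98). Of 12 BMP and TGF-beta genes 2 rose, with 2 also adjusted over the list alone (Id1 1.3, but −0.021 in the other class of cells with at least 1000 genes; Id3 0.70); their median of 0.38 became −0.08 with library totals. Of 7 Wnt pathway genes 1 fell, with 1 also adjusted over the list alone (Sfrp1, a secreted Wnt antagonist, −1.50). None of 5 atrioventricular canal patterning genes passed edgeR's test, over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0; Tbx20 stood at 0.11 (−0.87 in the other class of cells with at least 1000 genes), and the list's median of 0.11 became −0.35 with library totals, where 1 fell. Of 8 mitral valve disease genes 2 rose and 1 fell, with 2 and 1 adjusted over the list alone, among them Flna (1.34), an actin-binding protein mutated in X-linked valve dystrophy, and Lmcd1 (−1.83), and the median of 0.34 became −0.12 with library totals. Of 8 endothelial identity genes 1 rose, with 1 also adjusted over the list alone (Pecam1, 3.33, 13 UMIs), with the median of 0.04 becoming −0.41 with library totals. Of 3 flow-responsive genes 1 rose and 1 fell, with the same counts adjusted over the list alone, but 0 rose and 2 fell with library totals. These were Heg1 (1.80, but −0.077 with all libraries clustered together) and Klf4, which had 1 UMI against 53 at P0, a ratio of 0.0554 (0.00138 to 0.322).

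Among growth and metabolic lists, 7 of 13 oxidative phosphorylation genes rose, with 7 also adjusted over the list alone, led by the respiratory chain subunits Cox7a2 (2.15) and Cox6c (1.65), at percentile 94.3. Of 9 glycolysis genes 2 fell, with 2 also adjusted over the list alone (Aldoa −2.06, Ldha −0.94). Of 20 cell cycle genes 4 fell, or 5 with 2 rising adjusted over the list alone; Cenpf had 1 UMI at E16.5, a ratio of 0.0753 (0.00186 to 0.445), and Ccnb1 1 UMI, a ratio of 0.0917 (0.00225 to 0.549), though the log2 fold of Ccnb1 was 1.22 in the other class of cells with at least 1000 genes and 0.69 with all libraries clustered together, where the class took in pericyte-like cells. With library totals 8 cell cycle genes fell. Of 10 early embryonic RNA-binding and growth genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone, with a median of 1.21 (1.16 with genes at 0 UMIs set at their bound) at percentile 99.4. Igf2bp2, an RNA-binding protein of embryonic growth, rose (2.62), Dlk1 rose (2.37, but −2.40 without the mitochondrial limit, where 47 of 113 cells of P0 replicate 1 came from clusters without a name) and the imprinted non-coding RNA Meg3 fell (−1.75). Of 4 antigen presentation and interferon genes 0 passed edgeR's test, 2 had an unadjusted p under 0.05, DESeq2 called 0, 1 rose and 1 fell adjusted over the list alone, and 1 fell with library totals, with Ifitm3 at 0.50. The dissociation stress list had 9 of 14 genes falling, or 10 adjusted over the list alone and 14 with library totals, at percentile 0.02, among them Junb (−2.91) and Btg2 (−2.72).

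Among the large rises outside the lists were Fam221b (60 UMIs against 0, at least 58.7-fold), Ccdc167 (3.58), Ptgfrn (3.10), Toporsos (3.06), Anapc13 (3.01) and Uqcr11 (2.94, a small subunit of respiratory complex III). Toporsos lies antisense to Topors and the counting strand is not given, so its reads may belong to either. Myl7, a cardiomyocyte myosin light chain, had 35 UMIs against 0, and all cardiomyocyte markers together stood at 6.50 per 10000 at E16.5 against 0.930 and 0.890 at P0. Absent from the E16.5 sum were Zfand6 (at least 7.28-fold lower), Mbnl2 (6.82), Cldnd1 (6.69), Cdc42ep3 (6.44), Tiprl (5.93), Ddx21 (5.78), Zcchc9 (5.21) and Krit1 (4.83). Over the tested genes, which are not independent replicates, the 915 with the shortest transcripts (median 1107 nt) had a median log2 fold of 0.67, and the longest −0.54. DESeq2's Wald test called 251 higher and 92 lower, a higher share of 73.2%. Besides the counts above it called as higher 6 oxidative phosphorylation, 2 early embryonic and 1 disease genes, and as lower 1 Notch, 1 proteoglycan, 1 cell cycle, 1 glycolysis, 1 early embryonic and 4 dissociation stress genes, but no EndMT, BMP and TGF-beta, Wnt, basement membrane, identity or flow-responsive gene.

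The E9.5 mixed cluster was set against P0 interstitial-like cells to ask how canal cells at the start of valve formation differ from newborn leaflet mesenchyme. Most matrix genes were lower in it, and most measured endothelial, glycolysis and cell cycle genes were higher. Eln, elastin, had 1 UMI in 2157234 against 4.88 ± 0.384 per 10000 (SD, n = 2) at P0, a ratio of 0.000939 (0.0000237 to 0.00528). Col6a3, a collagen VI chain, had 0 UMIs against 78, at least 109.6-fold lower. Pkm, a glycolytic pyruvate kinase, stood at 13.5 (13.0 to 14.0) against 2.0 ± 0.286, and Hapln1, which links hyaluronan to proteoglycans in the cardiac jelly and also led this cluster against other E9.5 cells, at 12.3 (11.9 to 12.8) against 1.35 ± 0.540.

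By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Pkm rose with a log2 fold of 2.44 (SE 0.22, adjusted p 1.3e-26), the E9.5 library lying above both P0 libraries. Pkm is ENSMUSG00000032294 at chromosome 9, 59656368 to 59679375, Hapln1 is ENSMUSG00000021613 at chromosome 13, 89539796 to 89611652, Eln is ENSMUSG00000029675 at chromosome 5, 134702593 to 134747323, and Col6a3 is ENSMUSG00000048126 at chromosome 1, 90765923 to 90843971. In all, 903 genes rose and 958 fell of 3668, and with library totals 1408 rose and 697 fell, the higher share going from 48.5% to 66.9% and the median log2 fold from 0.02 to 0.39. The families described next kept their direction with library totals and with DESeq2 size factors unless stated.

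All 11 measured collagens fell, also adjusted over the list alone, with a median of −6.50 (−6.10 with genes at 0 UMIs set at their bound); Col12a1 was at least 55.2-fold lower and Col5a1 fell by 3.29. Of 12 proteoglycan genes 11 fell and Hapln1 rose (2.92), also adjusted over the list alone, with a median of −6.80 (−5.32 at the bound), and Aspn was at least 71.9-fold lower. Of 13 elastic fibre genes 12 fell, or 13 adjusted over the list alone; Fbln5, needed for elastic fibre assembly, had 1 UMI, a ratio of 0.00200 (0.0000502 to 0.0114). Of 6 cartilage, tendon and bone genes 4 fell and 1 rose, also adjusted over the list alone: Scx had 1 UMI, a ratio of 0.0127 (0.000304 to 0.0803), and Sox9 rose (0.70). Of 9 basement membrane genes 7 fell and 1 rose, also adjusted over the list alone (Lamb2 −3.24, Lamc1 −1.90, Col18a1 0.78), but 4 fell with library totals and DESeq2 called 1 lower. Of 8 disease genes 7 fell and 1 rose, also adjusted over the list alone, with Lmcd1 at −6.95; 5 fell with library totals, and DESeq2 called 2 lower and 1 higher.

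Of 8 endothelial identity genes 7 rose and 1 fell, also adjusted over the list alone, with a median of 3.02 at percentile 100; Pecam1 rose (3.69) and Fli1 fell (−1.25), and DESeq2 called 2 higher. The identity and matrix lists hold several class markers. Of 10 EndMT transcription factors 5 rose and 3 fell, also adjusted over the list alone (Snai1 2.29, Prrx2 1.91, Zeb1 −2.18, Prrx1 −6.58), while DESeq2 called 0 and 1. Of 5 canal patterning genes 2 rose and 2 fell, also adjusted over the list alone: Msx1, a homeobox factor of cushion-forming endocardium, rose (1.20) with Gata4 (0.94), while Tbx20 fell (−1.10) with Gata6 (−0.65). Of 4 Notch genes 3 fell, or 4 adjusted over the list alone (Notch2 −4.28, Heyl −4.04). Of 12 BMP and TGF-beta genes 5 rose and 4 fell, also adjusted over the list alone, and their median of −0.01 became 0.36 with library totals; the BMP-induced inhibitors Smad6 (3.32) and Id2 (1.95) rose, Tgfbr1 fell (−2.08) and Tgfb3 had 2 UMIs, a ratio of 0.0207 (0.00236 to 0.0844). Of 7 Wnt genes 5 fell, also adjusted over the list alone (Sfrp2 −6.81, Sfrp1 −5.48). Of 3 flow-responsive genes 1 fell, also adjusted over the list alone (Klf4 −1.53), and with library totals 1 rose and 1 fell and the median of −0.06 became 0.31.

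Of 20 cell cycle genes 17 rose, also adjusted over the list alone (Mcm2 3.42, Rrm2 2.69), though DESeq2 called 1. All 9 glycolysis genes rose, also adjusted over the list alone (Pfkl 3.13), at percentile 100. Of 13 oxidative phosphorylation genes 7 rose and 1 fell, also adjusted over the list alone (Atp5b 1.46, Cox6c −1.22). Of 10 early embryonic genes 5 rose and 1 fell, also adjusted over the list alone: the transcription factor Mycn had 239 UMIs against 2, a ratio of 27.3 (7.47 to 226), and Meg3 fell (−0.53). All 4 antigen presentation and interferon genes fell, also adjusted over the list alone (Ifitm3 −4.85, Irf1 with 3 UMIs). Of 14 dissociation stress genes 13 fell and 1 rose, also adjusted over the list alone (Egr1 −7.59, Fos −5.65, Hspa8 1.44). Among the largest changes were the chromatin protein Hmga2 (at least 50.3-fold higher), the cardiac factor Gata5 (25.4), Dusp9 (15.4), Plac1 (11.4) and Frrs1 (10.5). Lower at E9.5 were Mgp, an inhibitor of calcification (0 UMIs, at least 1233-fold), Dpt (382), Prss35 (181), Thbs2 (86.8) and Adamts2 (81.1). Myl7 and Tnni1 were at least 110.3-fold and 71.8-fold higher, and the mixed cluster held cardiomyocyte markers at 21.4 and haemoglobin genes at 85.3 per 10000. DESeq2's Wald test called 71 higher and 375 lower. Besides the counts above it called as lower 11 collagens, 10 proteoglycan, 9 elastic fibre, 3 cartilage, tendon and bone, 3 Notch, 3 Wnt, 1 BMP and TGF-beta, 1 oxidative phosphorylation, 3 antigen presentation and 11 dissociation stress genes, and as higher 4 glycolysis, 3 BMP and TGF-beta, 2 early embryonic, 1 oxidative phosphorylation, 1 proteoglycan and 1 dissociation stress genes, but no canal or flow-responsive gene.

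On the interstitial side E9.5 and E16.5 had 1 library each. Ratios of UMI shares with exact conditional binomial 95% intervals are given and nothing was tested. A gene counts as higher or lower here where its interval excludes a 2-fold change on at least 20 UMIs. All 10 measured collagens were higher at E16.5, Col5a1 21.1-fold (14.5 to 31.0) and Col6a3 at least 172-fold. Choosing clusters by matrix and endothelial markers fixed part of such changes. Mfap4, a microfibril protein that also led the E16.5 cluster, was 507-fold higher (214 to 1579), and Hapln1 was 23.0-fold lower (12.1 to 50.3). Cdkn1c, a cyclin-dependent kinase inhibitor with 10694 UMIs at E9.5, had 0 at E16.5, at least 277-fold lower. It is ENSMUSG00000037664 at chromosome 7, 143458339 to 143461050.

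Across 8219 genes 378 were higher and 744 lower at E16.5 with library totals, and 695 higher and 218 lower with TMM-scaled totals, so the higher share went from 33.7% to 76.1% and the median log2 ratio from −0.84 to −0.08. Higher were 6 of 10 proteoglycan genes (1 lower), 8 of 12 elastic fibre genes, 4 of 8 cartilage, tendon and bone genes, 4 of 9 disease genes (1 lower), 3 of 13 Wnt genes and 6 of 15 dissociation stress genes (1 lower). Examples were Fmod (at least 193-fold), Eln (88 UMIs against 1), Scx (34 against 1), Dkk3 (20.1-fold, 11.6 to 35.6) and Sfrp2 (59.2-fold, 22.0 to 199). Lower were 14 of 20 cell cycle genes (Hmgb2 19.8-fold, 11.3 to 38.4), 9 of 14 glycolysis genes (Aldoa 24.5-fold, 11.9 to 60.9) and 8 of 18 endothelial identity genes, whose median of −3.01 is −1.46 with genes at 0 UMIs at their bound. Of 10 EndMT factors 1 was higher (Snai2 6.74-fold, 2.93 to 14.6) and 2 lower (Msx1 8-fold, 4.04 to 18.6), of 15 BMP and TGF-beta genes 3 were lower (Id2 7.41-fold, 4.61 to 12.8), of 10 canal genes 1 was lower and of 8 flow-responsive genes 1 was lower (Klf2 3.22-fold, 2.13 to 5.10). With TMM-scaled totals 8 cell cycle, 5 glycolysis, 3 identity, 1 EndMT, 1 BMP and TGF-beta and no flow-responsive genes were lower, while 9 dissociation stress and 2 antigen presentation genes were higher. Of 14 oxidative phosphorylation genes 3 were higher (Cox6c 4.32-fold, 3.93 to 4.75) and 3 lower (Atp5b 4.55-fold, 3.48 to 6.05), and their median of −0.40 became 0.36 with TMM scaling. The medians of the EndMT (−0.69), Notch (−0.18) and BMP and TGF-beta (−0.40) lists likewise became 0.07, 0.57 and 0.36; with genes at 0 UMIs at their bound they were −0.44, 0.22 and −0.20 before that scaling. Of 12 early embryonic genes 4 were lower (median −1.27, or −0.68 at the bound), but 2 were higher and 1 lower with TMM scaling. Of 3 antigen presentation and interferon genes 1 was higher (Ifitm3 24.3-fold, 18.6 to 31.8), and 0 of 8 Notch and 0 of 11 basement membrane genes met the size rule, where 1 Notch and 4 basement membrane genes were higher with TMM scaling. Dpt (at least 429-fold) and Prss35 (249) were also higher, and Cd24a (at least 24.2-fold) lower.

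**Figure D3:**
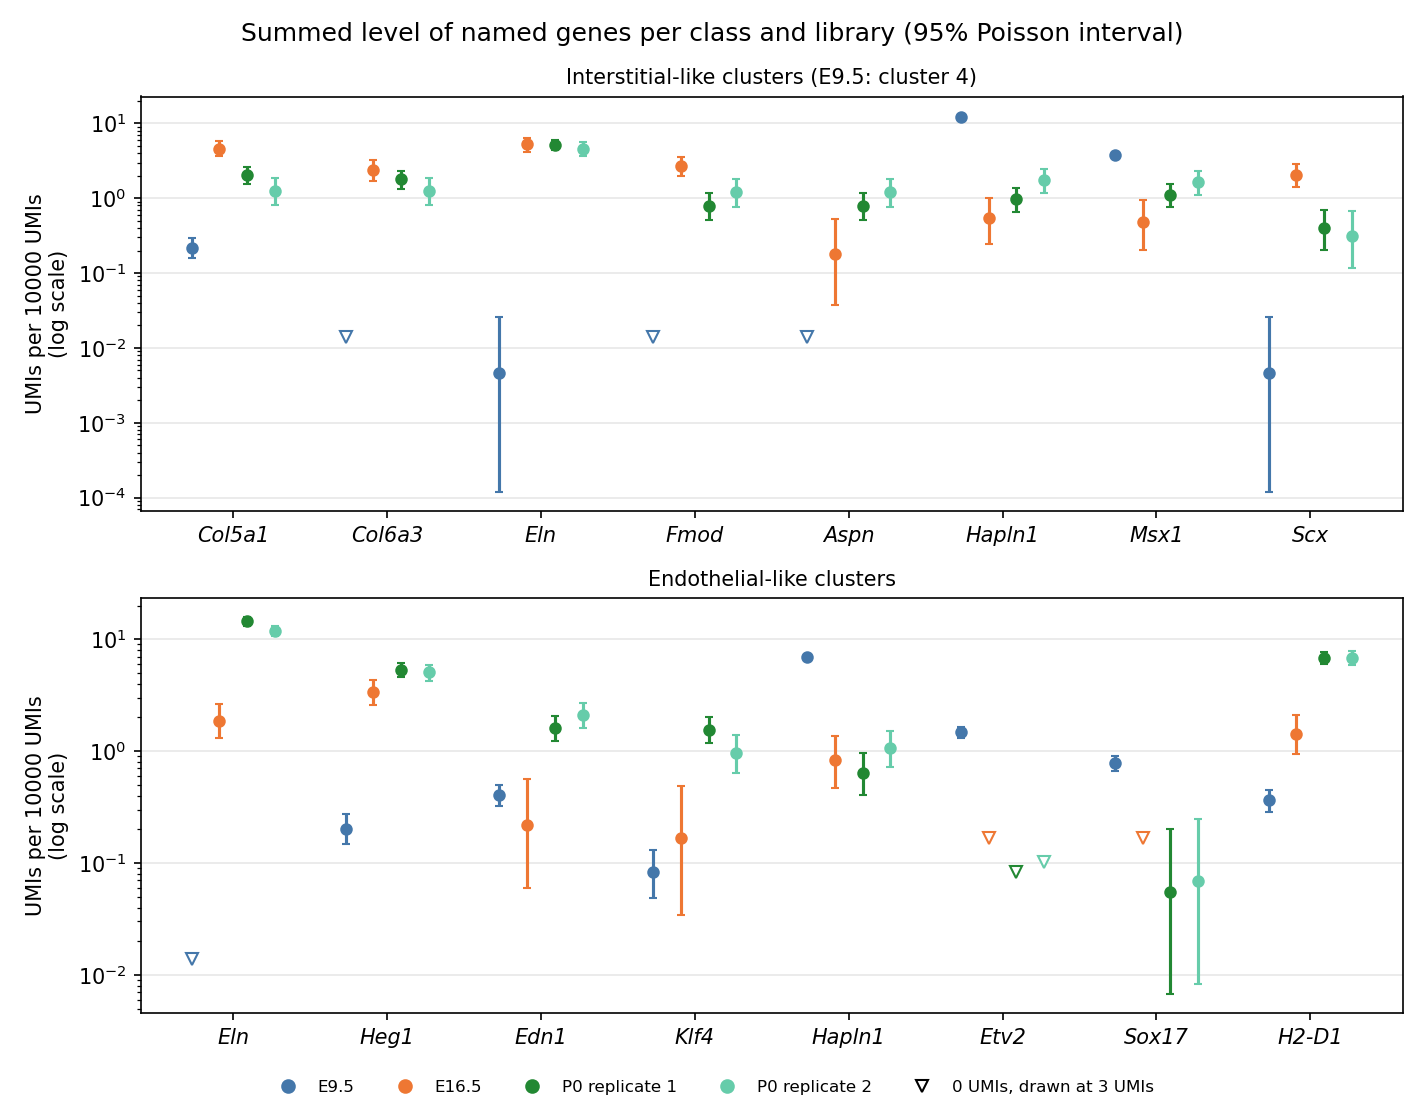
UMIs per 10000 UMIs (y axis, log scale) of 8 genes (x axis) in the interstitial-like clusters and the E9.5 mixed cluster (cluster 4, upper panel) and in the endothelial-like clusters (lower panel), 1 point per library with 95% Poisson intervals, open triangles marking 0 UMIs drawn at 3 UMIs. In endothelial-like cells Eln goes from 0 UMIs at E9.5 to 1.88 at E16.5 and a mean of 13.1 at P0, while Hapln1 is at 6.90 at E9.5 and 0.848 at P0.

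E16.5 and P0 endothelial-like cells were compared to ask how the valve's surface lining changes before birth. Elastin RNA in these cells stood at 1.88 per 10000 (1.3 to 2.62) at E16.5 against 13.1 ± 1.88 (SD, n = 2) at P0, where it was among the genes that led the endothelial-like cluster of replicate 1. Edn1, a vasoconstrictor peptide regulated by flow, stood at 0.221 (0.0601 to 0.565) against 1.86 ± 0.361. H2-D1, an MHC class I heavy chain, stood at 1.43 (0.937 to 2.1) against 6.80 ± 0.00420. Ndufa4, a respiratory chain subunit, stood at 23.9 (21.7 to 26.2) against 8.40 ± 0.825.

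By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Eln fell with a log2 fold of −2.31 (SE 0.36, adjusted p 1.1e-08) and Ndufa4 rose with 2.0 (SE 0.27, adjusted p 3.6e-11), each E16.5 value lying outside both P0 libraries. Edn1 fell by 2.57 in log2 (SE 0.61) and H2-D1 by 1.75 (SE 0.38), also on the same side of both P0 libraries. Edn1 is ENSMUSG00000021367 at chromosome 13, 42301476 to 42307990, and H2-D1 is ENSMUSG00000073411 at chromosome 17, 35262730 to 35267499. H2-D1 and H2-K1 are similar in sequence, so the assignment of reads between them is uncertain. In all, 539 genes rose and 439 fell of 4117, and with library totals 274 rose and 891 fell, the higher share going from 55.1% to 23.5% and the median log2 fold from −0.15 to −0.70. With every cell thinned to 1000 UMIs edgeR called 0 genes higher and 1 lower, 400 of 1386 genes having an unadjusted p under 0.05; DESeq2's Wald test on all UMIs called 262 higher and 67 lower, among them 6 oxidative phosphorylation, 2 early embryonic, 1 basement membrane and 1 elastic fibre genes higher and 1 BMP and TGF-beta, 1 cell cycle, 1 antigen presentation and 1 elastic fibre genes lower, but no Notch, collagen, identity or flow-responsive gene.

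Of 13 oxidative phosphorylation genes 7 rose and 1 fell, or 10 and 1 adjusted over the list alone (Cox7a2 1.92, Uqcrc2 with 1 UMI). The median of 1.12 lay at percentile 94.3, again without matching on length. Of 6 antigen presentation and interferon genes 2 fell, or 3 adjusted over the list alone, with a median of −1.96 (−1.38 at the bound) at percentile 0.38; H2-K1 had 1 UMI, a ratio of 0.0414 (0.00104 to 0.237). Of 10 elastic fibre genes 2 rose and 1 fell, also adjusted over the list alone, the microfibril genes Emilin1 (1.42) and Mfap2 (1.35) rising while Eln fell, and with library totals 1 rose and 2 fell. Of 9 flow-responsive genes 2 fell, also adjusted over the list alone (Edn1 and Klf4, a ratio of 0.129 on 3 UMIs, 0.0260 to 0.389). Of 3 Notch genes 1 fell, also adjusted over the list alone (Hes1 −1.66). Of 12 BMP and TGF-beta genes 1 rose and 1 fell, also adjusted over the list alone (Id3 0.79, Id2 −1.63), and with library totals 5 fell. Of 20 cell cycle genes 2 fell, or 1 adjusted over the list alone: Hmgb2 (−1.94) and Ccnb2, with 1 UMI; with library totals 5 fell, and with DESeq2 size factors 2 rose and 2 fell. Of 11 early embryonic genes 4 rose and 2 fell, also adjusted over the list alone (Igf2bp2 2.82, Igf2bp1 2.33, Meg3 −1.09), and with library totals 1 rose and 2 fell. At Leiden resolution 2.0 Igf2bp1 stood at −6.25 and Meg3 at 0.33, and Meg3 at 0.052 among cells with at least 1000 genes clustered again. In the cells of the endothelial-like clusters used here with at least 1000 genes the ratio of Meg3 was 0.364 (0.164 to 0.706). Of 14 dissociation stress genes 1 rose and 4 fell, also adjusted over the list alone (Hspa8 0.83, Dusp1 −2.08, Jun −1.3), while with library totals 6 fell and DESeq2 called 1 higher.

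Of 7 collagens 1 rose, also adjusted over the list alone (Col1a2 1.05, a class marker, but −0.37 at Leiden resolution 2.0), and of 10 basement membrane genes 1 rose, also adjusted over the list alone (Col18a1 1.21); with library totals 0 collagens passed and 1 basement membrane gene fell, the basement membrane median going from 0.39 to −0.17, and with DESeq2 size factors 2 collagens rose. Of 18 endothelial identity genes 1 rose and 1 fell (Ecscr 0.81, Fli1 −1.48), but 0 and 0 adjusted over the list alone, and with library totals 5 fell and the median went from 0.02 to −0.48, whereas with DESeq2 size factors 2 rose. No member of 5 lists passed edgeR's test over all genes or adjusted over the list alone: 3 EndMT factors (0 with an unadjusted p under 0.05; Zeb1 0.28), 5 canal genes (1; Hand2 0.87), 6 Wnt genes (1; Nkd1 0.21), 6 proteoglycan genes (0; Bgn 0.04) and 11 glycolysis genes (3; Gapdh 0.25). DESeq2 called 0 of each, and of the 8 disease genes 0 passed either tool with 2 at an unadjusted p under 0.05 (Sptbn1 −0.77). Other scalings changed this. With library totals 2 glycolysis, 2 disease, 1 Wnt and 1 proteoglycan genes fell, and with DESeq2 size factors in edgeR 1 canal and 1 glycolysis gene rose. The canal, glycolysis and disease medians (0.12, 0.29 and 0.34) became −0.43, −0.27 and −0.22 with library totals; the Wnt median of −0.02 became 0.05 with DESeq2 size factors. No cartilage, tendon and bone gene was measured. Rises outside the lists included Gata3 (41 UMIs against 1, a ratio of 148, 25.1 to 5978), Fam221b (76 against 3, a ratio of 91.3, 30.1 to 453), Cnot3 (3.66), Apoc1 (3.58), Zkscan1 (3.31), Myl7 (2.91) and Ndufb4 (2.90), and cardiomyocyte markers stood at 6.46 per 10000 against 1.36 and 2.36 at P0. With 0 UMIs at E16.5, Eif5b was at least 14.5-fold lower, Prpf4b 8.30, the transcription factor Mef2c 7.53, Ppp4r2 5.92, Cdc42ep3 5.61, Vgll4 5.51 and Slc26a10 5.40.

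E9.5 endothelial-like cells were set against P0 to ask how canal endocardium differs from the newborn valve lining. The E9.5 cells lacked elastin RNA (0 UMIs in 2173747 against 866 at P0, at least 950-fold lower). Etv2, a factor that initiates endothelial fate, had 320 UMIs against 0 (at least 32.1-fold higher), and Sox17, an endothelial and endodermal factor, stood at 0.782 (0.669 to 0.909) against 0.0619 ± 0.00911 (SD, n = 2). Heg1, a receptor that stabilises endothelial junctions in the heart, stood at 0.202 (0.147 to 0.272) against 5.19 ± 0.189. Ldha, lactate dehydrogenase, stood at 26.2 (25.6 to 26.9) against 3.02 ± 0.660.

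By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Heg1 fell with a log2 fold of −4.82 (SE 0.37, adjusted p 3.0e-36) and Ldha rose with 2.97 (SE 0.27, adjusted p 1.6e-25), each E9.5 value lying outside both P0 libraries. Heg1 is ENSMUSG00000075254 at chromosome 16, 33684370 to 33771576, Etv2 is ENSMUSG00000006311 at chromosome 7, 30633616 to 30635852, and Sox17 is ENSMUSG00000025902 at chromosome 1, 4490931 to 4497354. In all, 1065 genes rose and 999 fell of 4117, and with library totals 1209 rose and 818 fell, while every list below kept its direction. Thinned to 1000 UMIs per cell edgeR called 0 higher and 1 lower, 462 of 1386 genes having an unadjusted p under 0.05. DESeq2's Wald test on all UMIs called 138 higher and 362 lower, a higher share of 27.6% against 51.6%. It called as lower 8 flow-responsive, 6 basement membrane, 6 collagen, 5 identity, 5 elastic fibre, 5 disease, 4 proteoglycan, 3 BMP and TGF-beta, 2 Wnt, 2 Notch, 4 antigen presentation and 8 dissociation stress genes, and as higher 7 glycolysis, 2 oxidative phosphorylation, 1 identity, 1 proteoglycan and 1 dissociation stress genes, but no EndMT or canal gene.

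All 9 flow-responsive genes fell, also adjusted over the list alone, with a median of −2.85 at percentile 0, including the shear-induced factors Klf2 (−1.84) and Klf4 (−4.06), Nos3 (−1.50) and Thbd (−3.68). Of 18 endothelial identity genes 3 rose and 11 fell, or 3 and 12 adjusted over the list alone (Sox17 3.49, Pecam1 −1.68), at percentile 0.280. Of 10 basement membrane genes 9 fell, also adjusted over the list alone (Lamb2 −4.83, Lama4 −2.98). Of 7 collagens 6 fell, also adjusted over the list alone (Col6a1 at least 45.0-fold lower, Col5a1 −4.28). Of 6 proteoglycan genes 4 fell and Hapln1 rose (2.89), also adjusted over the list alone. Of 10 elastic fibre genes 7 fell and 2 rose, also adjusted over the list alone (Fbn2 0.86, but −0.12 at Leiden resolution 0.5). Of 12 BMP and TGF-beta genes 7 fell, also adjusted over the list alone (Tgfbr2 −3.61, Tgfbi −3.43), as did 5 of 6 Wnt genes (Wnt2 −3.64, Wnt9b at least 28.9-fold lower) and 2 of 3 Notch genes (Hes1 −1.98, Notch1 −1.87), each also adjusted over the list alone. Of 3 EndMT factors 1 rose (Msx1 2.03) and of 5 canal genes 1 rose and 1 fell (Hand2 −1.45), also adjusted over the list alone. Of 8 disease genes 7 fell and 1 rose, also adjusted over the list alone (Plvap 1.06, a class marker).

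Of 20 cell cycle genes 17 rose, also adjusted over the list alone (Rrm2 3.72, Mcm5 2.83), with 6 called by DESeq2. Of 11 glycolysis genes 10 rose and 1 fell, also adjusted over the list alone: Slc2a1, a glucose transporter, rose (3.50) and Pgk1 fell (−1.62). Of 13 oxidative phosphorylation genes 7 rose, also adjusted over the list alone (Atp5b 1.73, Uqcrc2 1.71). Of 11 early embryonic genes 5 rose and 3 fell, also adjusted over the list alone: Igf2bp1 rose (3.65), while the imprinted growth genes Igf2 (−3.48) and H19 (−1.64) fell, while DESeq2 called 1 higher and 2 lower. Of 6 antigen presentation and interferon genes 4 fell, also adjusted over the list alone (H2-D1 −4.37, H2-K1 −5.64). Of 14 dissociation stress genes 10 fell and 1 rose, or 11 and 1 adjusted over the list alone (Hspa8 2.5, Fos −3.92, Egr1 −3.33). Among the largest changes were Hmga2 (920 UMIs against 3, a ratio of 92.2, 31.4 to 448), Mogat2 (at least 25.6-fold higher) and Igfbp2 (15.5), and Mfap5 (at least 240-fold lower), Nppc (122), Palmd (108) and Pthlh (104). Haemoglobin genes took 67.4 and cardiomyocyte markers 18 per 10000 UMIs of the E9.5 endothelial-like sum, beside the rise of Acta2 (at least 26.1-fold).

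From E9.5 to E16.5, with 1 library on each side and no test, some flow-responsive and basement membrane genes were higher in the endothelial-like cells. Heg1 was 16.6-fold higher at E16.5 (11.1 to 25.1), Lamb2, a laminin chain, 32.6-fold (13.1 to 91.6), and Eln at least 136-fold, while Etv2 was at least 8.89-fold and Sox17 at least 4.72-fold lower. Cdkn1c, which led the E9.5 cluster, was 29.4-fold lower (20.6 to 43.6) and Hapln1 8.33-fold lower (5.04 to 14.9). Of 8166 genes 370 were higher and 800 lower, and with TMM-scaled totals 643 were higher and 271 lower, so the higher share went from 31.6% to 70.4% and the median log2 ratio from −0.74 to −0.10.

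Higher were 4 of 4 collagens (Col5a1 25.1-fold, 11.7 to 57), 4 of 7 proteoglycan genes (1 lower), 5 of 10 elastic fibre genes, 5 of 11 basement membrane genes (Lama4 6.26-fold, 3.65 to 10.5), 3 of 8 flow-responsive genes (Thbd 8-fold, 4.15 to 15.1) and 3 of 8 disease genes (Tns1 9.74-fold, 4.31 to 21.6). Also higher were 1 of 9 Notch genes (Jag1 7.71-fold, 2.94 to 19.1), 2 of 16 BMP and TGF-beta genes with 1 lower (Tgfbr2 5.14-fold, 2.61 to 9.66), 3 of 4 antigen presentation and interferon genes (Ifitm3 14.7-fold, 11.8 to 18.4) and 4 of 14 dissociation stress genes with 1 lower. Lower were 15 of 20 cell cycle genes and 8 of 14 glycolysis genes (Ldha 11.6-fold, 8.54 to 16.2). Of 18 identity genes 2 were higher (Tie1 2.79-fold, 2.07 to 3.71) and 2 lower, of 7 canal genes 1 was higher (Hand2 3.17-fold, 2.23 to 4.43) and 1 lower, and of 7 EndMT factors 2 were lower. With TMM-scaled totals 9 cell cycle, 6 glycolysis and 1 EndMT genes were lower, and 6 identity, 6 flow-responsive, 6 disease, 6 dissociation stress and 3 BMP and TGF-beta genes were higher. Of 14 oxidative phosphorylation genes 3 were higher and 2 lower (Cox6c 2.90-fold higher, Atp5b 4.99-fold lower), their median of −0.07 becoming 0.58 with TMM scaling. The medians of the EndMT (−0.24), canal (−0.09), BMP and TGF-beta (−0.10) and Wnt (−0.45, or 0 at the bound) lists likewise became 0.41, 0.56, 0.55 and 0.20. Of 13 early embryonic genes 3 were higher (Igf2 7.43-fold, 6.58 to 8.38) and 5 lower (Hmga2 at least 25.6-fold), but 3 and 2 with TMM scaling. Of 8 Wnt genes 0 met the size rule (Nkd1 1.94-fold, 0.925 to 3.69), and the single measured cartilage, tendon and bone gene, Sox9, did not meet it (3.75-fold, 1.07 to 10.7, but a log2 ratio of −2.20 at Leiden resolution 0.5 and with all libraries clustered together, where nearly all of the mixed cluster joined the E9.5 endothelial-like cells). Npm1 was 15.8-fold (11.6 to 22.0) and Eif5b at least 15.2-fold lower, and Mfap5 at least 276-fold and Fabp4 at least 152-fold higher.

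**Figure D4:**
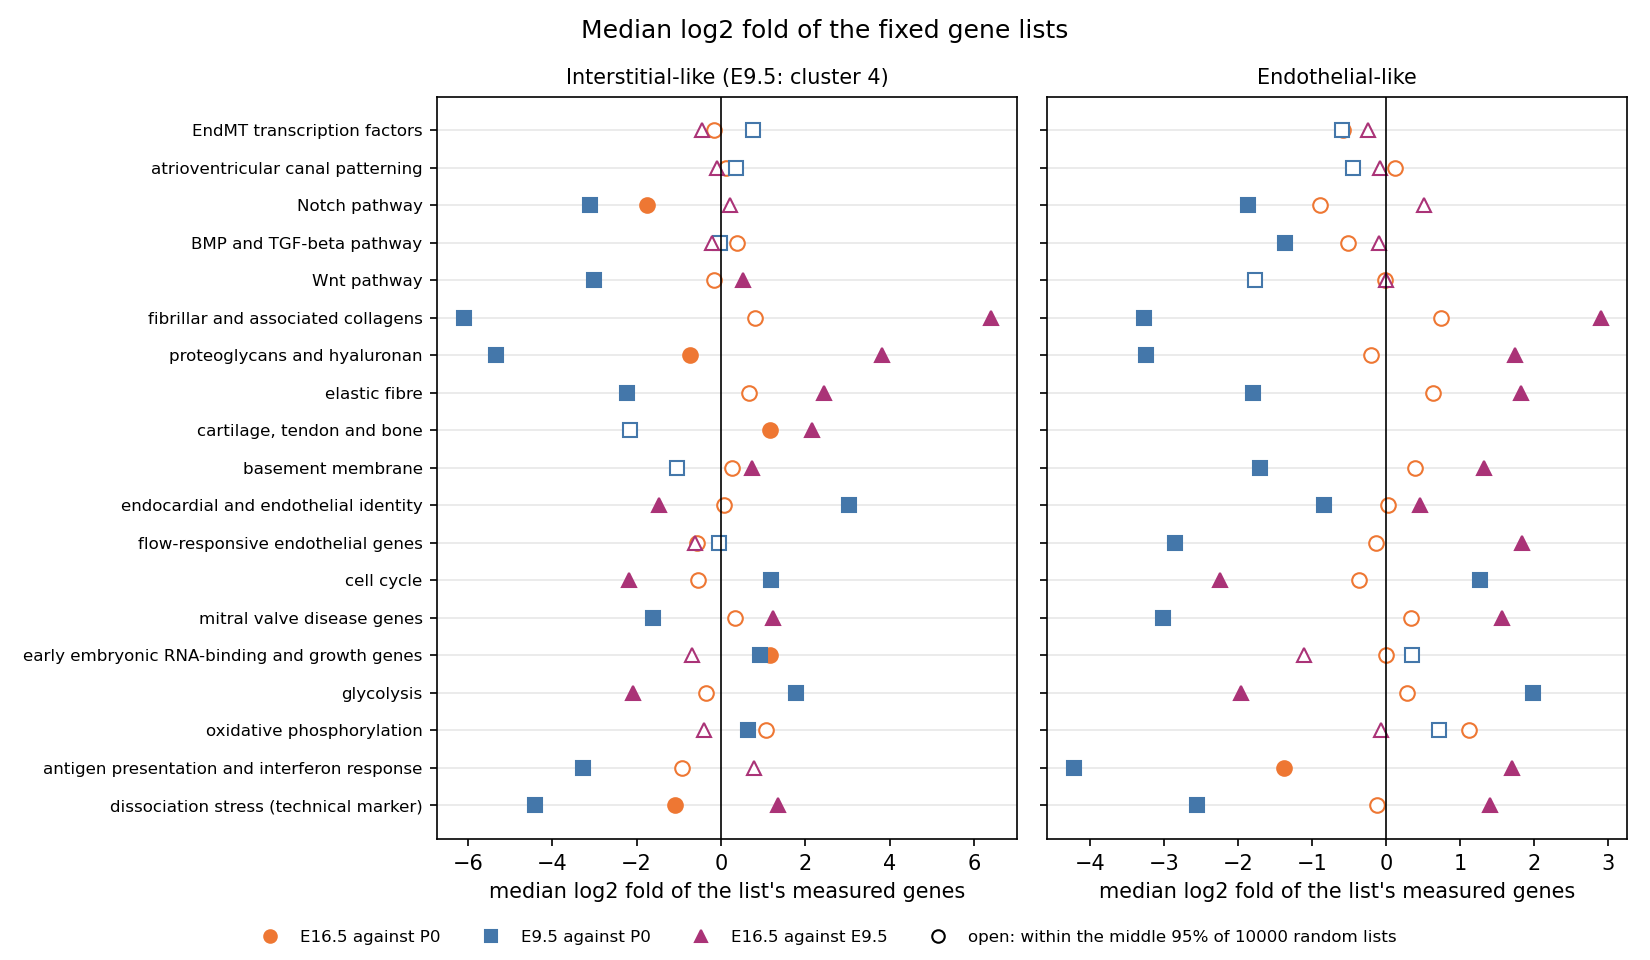
Median log2 fold (x axis) of the measured members of each fixed gene list (y axis) in the interstitial-like comparisons (left; E9.5 is the mixed cluster) and the endothelial-like comparisons (right), genes at 0 UMIs set at their bound, filled where the median lies outside the middle 95% of 10000 random lists. Collagen medians lie at −6.10 and 6.4 around E9.5 on the left and cell cycle medians fall from E9.5 to E16.5 on both sides. Without that bound, medians near 0 change sign with the scaling. On the left these are BMP and TGF-beta (all 3 comparisons), canal, basement membrane, identity and disease (E16.5 against P0) and flow (E9.5 against P0). For E16.5 against E9.5 they are also EndMT, Notch and oxidative phosphorylation. On the right, E16.5 against P0 has canal, basement membrane, identity, disease, glycolysis and Wnt. E16.5 against E9.5 has EndMT, canal, BMP and TGF-beta, Wnt and oxidative phosphorylation.

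Cell cycle genes were summed per class as a share of UMIs, so that depth per cell sets no threshold. The list took 116.7 UMIs per 10000 (115.3 to 118.2) in the E9.5 mixed cluster, 26.7 (24.3 to 29.3) in E16.5 interstitial-like cells and 44.8 (42.4 to 47.2) and 56.7 (53.4 to 60.2) at P0. Endothelial-like cells had 122.5 (121.0 to 124.0) at E9.5, 24.8 (22.6 to 27.2) at E16.5 and 45.5 (43.3 to 47.8) and 45.6 (43.2 to 48.2) at P0. The E16.5 value was the lowest in both classes, but at E16.5 the smooth muscle or pericyte-like cluster, led also by Ube2c, Cks2, Mki67 and Cdk1, had 81.6 (76.6 to 86.7), and all kept E16.5 cells together had 42.0. In the cells of these clusters with at least 1000 genes the list stood at 36.5 (29.9 to 44.0; 7 cells) in E16.5 interstitial-like cells against 45.6 (43.2 to 48.1) and 57.2 (53.8 to 60.8) at P0. In endothelial-like cells it stood at 36.3 (32.4 to 40.5; 20 cells) against 45.5 and 46.0. Clustered again, the 33 cells with the interstitial name had 84.7, 15 of them from that pericyte-like cluster.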

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

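The test of class differences, the comparison of UMI totals between E9.5 clusters and the level of Malat1 in the deeper cells of the E16.5 cluster were chosen only after the result was seen, and the RNA class levels of each library, including Malat1 in capillary cells, were known before the E16.5 tests were run. The change from P0 to E16.5 differed between interstitial-like and endothelial-like cells for 20 of 4383 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, library taken as a block with 1 residual degree of freedom, and 440 genes had an unadjusted p under 0.05. Of these, 12 were higher in interstitial-like cells and 8 in endothelial-like cells. For elastin (Eln) the interstitial minus endothelial difference in log2 fold was 2.87 (SE 0.41, adjusted p 8.0e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), the E16.5 library lying at 0.53 in interstitial-like and −2.33 in endothelial-like cells against both P0 libraries. For Fbln2, a fibulin of elastic fibres, it was 2.07 (SE 0.46), from 1.42 and −0.63. For Btg2, an early response gene, it was −3.34 (SE 0.70), from −2.66 and 0.60. For Pecam1, an endothelial adhesion molecule, it was 3.26 (SE 0.82), resting on 2 and 3 UMIs in the interstitial-like sums at P0. The fitted differences of Ppp4r2 (10.44), Myl7 (7.79) and the transcription factor Gata3 (−4.84) rest on sums of 0 UMIs, for Gata3 on 0 and 1 UMI in the endothelial-like sums at P0, and depend on the prior count.

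The E16.5 library stood apart from the P0 libraries in its RNA classes, with Malat1 at 6.70 UMIs per 10000 against 344 and 332 at P0. At E9.5, in cells with at least 1000 genes, Malat1 stood at 25.6 in the mixed cluster and 17.6 in endothelial-like cells. A level far below P0 was thus not particular to E16.5. Poorly captured cells are argued against as the whole cause, because in the 7 cells of the E16.5 interstitial-like cluster with at least 1000 genes Malat1 stood at 7.09 (95% Poisson interval 4.39 to 10.8) against 457 and 441 in such P0 cells, a log2 ratio of −5.99 (−6.68 to −5.38), and it was −5.73 (SE 0.17) when cells with at least 1000 genes were clustered again, though only 4 of those 33 E16.5 cells came from that cluster. A loss of long transcripts stays open: across 3664 genes, which are not independent, the log2 fold correlated with the longest annotated transcript at a Spearman coefficient of −0.29 (bootstrap 95% interval −0.32 to −0.26), and at −0.28 without ribosomal protein and mitochondrial genes, but E9.5 against P0 also gave −0.10 in the mixed cluster and −0.22 in endothelial-like cells (−0.36 there at E16.5), so it is not particular to E16.5. A shift common to all cells of that library stays open too, since 94.4% (92.8 to 95.7) of 1021 interstitial calls had the same sign in capillary or coronary endothelial-like cells. A change with age in every cell type may give the same pattern, and library and stage coincide, so a biological cause was not tested apart from these.

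At E9.5, 41.6% of cells sorted for an endothelial lineage reporter were cardiomyocyte-like. Cardiomyocyte markers stood at 720.0 per 10000 in these clusters and 20.4 in erythroid-like cells, a ratio of 35.4 (34.8 to 35.9). The clusters were named by these same markers, counted from 2-fold, so some excess was fixed by the naming, but not one of this size. Free cardiomyocyte RNA is argued against as the only source. Endothelial markers stood at 1.13 per 10000 there, 3.53% (3.33 to 3.75) of the 31.9 in the endothelial-like cluster, with median UMIs of 23333.5 and 22552. A cluster with most endothelial markers raised would not have taken the cardiomyocyte name, and cells scored as doublets had been left out. The low level was thus partly fixed, and it shows only that the cells so named held little endothelial RNA. A sort that let unlabelled cells pass, or reporter activity outside the lineage, could give cardiomyocyte-like cells and was not tested, since the reporter is not in the gene table. No biological explanation was tested.

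The E9.5 mixed cluster carried endothelial markers at 13.0 and interstitial markers at 9.86 UMIs per 10000, against 31.9 and 2.25 in the endothelial-like cluster. Doublets of endothelial and mesenchymal cells are argued against, because its median of 22110.5 UMIs per cell was 0.980 (bootstrap 95% interval 0.799 to 1.14) times that of the endothelial-like cluster. A mixture of separate cells stays open, since the marker set shares of its 102 cells were correlated at −0.64 (−0.74 to −0.51). Shares this small hardly oppose each other through a common total. All 102 cells had UMIs of both sets, as did 91 of 243 erythroid-like cells, which have a median of 32399 UMIs. A gradual passage from endothelial to mesenchymal state may give the same correlation, as a hypothesis that these data do not separate from a mixture.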

How the results depend on the processing

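The fits without ribosomal protein genes, mitochondrially encoded genes and Malat1 and the fits without the E16.5 or E9.5 library were chosen only after the results were seen, as were the levels in deeper cells without clustering again, and the counts of called genes they gave stayed within 1.5 times the reported ones. Of the values of named genes under the alternatives, 757 of interstitial E16.5 against P0 counted as unchanged, 101 kept direction but lost the call, 2 gained it and 7 reversed. Unchanged means the same direction and side of the threshold, or a change of sign in a gene called in neither fit. Without a P0 replicate no threshold was checked, and only a called gene that changed sign counted as reversed. Named genes not tested in a setting are left out, so these numbers do not measure stability over all named genes. The like numbers were 846, 41, 0 and 0 for interstitial E9.5 against P0, 417, 22, 2 and 0 for interstitial E16.5 against E9.5, 620, 108, 3 and 4 for endothelial E16.5 against P0, 761, 42, 0 and 1 for endothelial E9.5 against P0, and 554, 37, 0 and 2 for endothelial E16.5 against E9.5. Called genes on opposite sides occurred with at least 1000 genes per cell (6 of interstitial E16.5 against P0) and at Leiden resolution 0.5 (1 of endothelial E9.5 against P0). No paired analysis was possible because the labels pair no libraries, no comparison had 3 libraries on a side, and a minimum of 500 UMIs per cell changed nothing after the filter on genes. Depth limits the E16.5 side most: its sums of 167649 and 181246 UMIs leave genes under about 1 UMI per 10000 with few counts. The cause of the changes below was not tested unless stated.

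Lists outside the middle 95% of random lists numbered 5 (interstitial E16.5 against P0), 13 (interstitial E9.5 against P0), 11 (interstitial E16.5 against E9.5), 1 (endothelial E16.5 against P0), 13 (endothelial E9.5 against P0) and 11 (endothelial E16.5 against E9.5). With at least 1000 UMIs per cell they numbered 3 in interstitial and 2 in endothelial E16.5 against P0, E16.5 shares were 7.69% smooth muscle or pericyte-like and 9.29% macrophage-like, and cell cycle genes at E16.5 stood at 28.4 per 10000 UMIs in endothelial-like and 22.8 in interstitial-like cells. With no mitochondrial limit the E16.5 against P0 lists numbered 2 and 2, interstitial Dlk1 reversed to −2.40, 558 genes were higher in interstitial E9.5 against P0, and shares were 9.33% (endothelial-like, E9.5), 8.12% (cardiomyocyte-like, E16.5) and 39.2% (interstitial-like, P0 replicate 1) and 2.33% (epicardial-like, E9.5). Cell cycle genes then stood at 29.6 (E16.5), 119.7 (E9.5), 49.9 and 41.9 (P0) in endothelial-like cells, and at 30.2 (E16.5), 119.7 (mixed cluster) and 52.0 (P0 replicate 1) on the interstitial side. Without doublet removal 3 lists passed in interstitial E16.5 against P0, endothelial-like cells made up 9.92% at E9.5, no cell of P0 replicate 1 was macrophage-like, and cell cycle genes stood at 120.8 (endothelial-like, E9.5) and 30.3 (interstitial-like, E16.5).

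With at least 1000 genes per cell Tbx20 (−0.87), Id1 (−0.021), Fmod (−1.29) and Ccnb1 (1.22) reversed in interstitial and Meg3 (0.052) in endothelial E16.5 against P0. The cells were clustered again, and of the 33 interstitial-like E16.5 cells 4 came from the main cluster of that name. This is another class, and depth is not shown to be the cause. In the 7 cells of the main cluster with at least 1000 genes the ratios to P0 were 1.53 (0.398 to 4.21) for Fmod, 1.58 (0.558 to 3.64) for Id1 and 0.691 (0.312 to 1.34) for Tbx20, and Ccnb1 had 1 UMI. Cell cycle genes stood at 36.5 there and 36.3 in such endothelial-like cells. Endothelial E16.5 against P0 then had 289 genes higher, 243 lower and 0 lists and E9.5 against P0 571 and 541, on fewer genes. Endothelial E16.5 against E9.5 had 312 lower. E16.5 shares became 40.7% interstitial-like, 6.17% cardiomyocyte-like and 29.6% capillary or coronary endothelial-like, and cell cycle genes stood at 42.2 (endothelial-like, E16.5), 42.5 (endothelial-like, P0 replicate 2) and 84.7 (interstitial-like, E16.5). At resolution 0.5 no E9.5 cluster could stand on the interstitial side, 2 lists passed in interstitial E16.5 against P0, Fbn2 (−0.12, endothelial E9.5 against P0) and Sox9 (−2.20, endothelial E16.5 against E9.5) reversed, and shares were 16% (endothelial-like, E9.5), 29.9% and 40.2% (endothelial-like and interstitial-like, P0 replicate 1), 25.8% (smooth muscle or pericyte-like, E16.5) and 0 (epicardial-like, E9.5, and macrophage-like, P0 replicate 1). Cell cycle genes then stood at 119.6 (endothelial-like, E9.5), 35.2 (interstitial-like, E16.5) and 52.0 (interstitial-like, P0 replicate 1).

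With all libraries clustered together no endothelial comparison with P0 and no E9.5 interstitial comparison could be made. Interstitial E16.5 against P0 then had 939 genes higher, 740 lower and 3 lists, Heg1 (−0.077) and Ccnb1 (0.69) reversed in it, and Sox9 (−2.20) reversed in endothelial E16.5 against E9.5. Endothelial-like shares were 15.9% at E9.5 and 0% in both P0 replicates, interstitial-like shares 55.2% at E16.5 (76 of 171 cells from the main interstitial-like cluster) and 40.2% and 40.3% at P0, no cell was epicardial-like, macrophage-like or smooth muscle or pericyte-like, and cell cycle genes stood at 119.8 (endothelial-like, E9.5), 49.2 (interstitial-like, E16.5) and 52.0 (interstitial-like, P0 replicate 1). At resolution 2.0, 456 genes were lower in interstitial and 457 in endothelial E16.5 against E9.5 (7 lists in the latter), endothelial E16.5 against P0 had 303 higher, 220 lower and 2 lists, and endothelial E9.5 against P0 577, 497 and 8. Col1a2 (−0.37), Igf2bp1 (−6.25) and Meg3 (0.33) reversed in endothelial E16.5 against P0. Shares were then 33.2% and 2.35% (cardiomyocyte-like and epicardial-like, E9.5), 3.23% (smooth muscle or pericyte-like, E16.5), 11.6% and 15.8% (endothelial-like and interstitial-like, E16.5), 13.2% (endothelial-like, P0 replicate 1), and 11.9% and 17.0% (endothelial-like and interstitial-like, P0 replicate 2). Cell cycle genes stood at 18.9 (E16.5), 119.9 (E9.5), 57 and 60.9 (P0) in endothelial-like cells and 119.2 in the mixed cluster.

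With cells thinned to 1000 UMIs, interstitial E16.5 against P0 had 228 genes higher, 142 lower and 1 list, interstitial E9.5 against P0 189, 232 and 7, interstitial E16.5 against E9.5 145, 212 and 5, and endothelial E16.5 against E9.5 131, 197 and 3, with fewer genes tested. Endothelial E16.5 against P0 and E9.5 against P0 each had 0 higher and 1 lower in edgeR, with 400 and 462 genes at an unadjusted p under 0.05 and prior degrees of freedom of 1.495, a loss of pooling between genes; DESeq2 was not run on thinned cells. With library totals interstitial E16.5 against P0 had 374 higher and 867 lower, interstitial E9.5 against P0 1408 higher, and endothelial E16.5 against P0 274 and 891. DESeq2's Wald test gave 251 and 92, 71 and 375, 262 and 67, and 138 and 362 for interstitial E16.5, interstitial E9.5, endothelial E16.5 and endothelial E9.5 against P0. With no low-count filter 3 lists passed in endothelial E16.5 against P0 and 1910 genes were higher in endothelial E9.5 against P0. For E16.5 against E9.5, a minimum of 5 UMIs gave 584 interstitial genes higher, TMM-scaled totals 695 higher and 218 lower (interstitial) and 643 and 271 (endothelial), and a 1.5-fold limit 1283 and 1363 lower. Leaving out a P0 replicate left no residual degree of freedom, so only ratios with counting intervals were taken. List numbers then ranged from 5 to 5 (interstitial E16.5), 13 to 13 (interstitial E9.5), 0, without replicate 1, to 1 (endothelial E16.5) and 12 to 13 (endothelial E9.5).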

Other observations

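The values in this part were picked after the clusters had been seen, and nothing in it was tested. The E9.5 cardiomyocyte-like clusters differed in genes of the atrioventricular canal. Bmp2, the myocardial signal that starts cushion formation, stood at 2.07 and 2.78 UMIs per 10000 in clusters 1 and 5 against 0.176 and 0.106 in clusters 3 and 11. The canal repressor Tbx2 stood at 0.439 and 0.862 against 0.0298 and 0.0676, and Msx2 at 0.777 and 1.98 against 0.0434 and 0.0483. Nppa, a natriuretic peptide of chamber muscle, ran the other way, at 1.85 and 0.471 against 13.7 and 34.0. The mixed cluster (cluster 4) had more Msx1 (3.82), Sox9 (2.73), Twist1 (1.71) and Has2 (0.440) than the endothelial-like cluster (1.05, 0.0736, 0.225 and 0.166), while Npr3 was lower (0.464 against 1.33). An E9.5 epicardial-like cluster, 7.47% of kept cells, held Wt1 at 1.71 and Tbx18 at 2.76, but the share was 2.33% without the mitochondrial limit, 2.35% at Leiden resolution 2.0, and 0 at resolution 0.5 and with all libraries clustered together. An E9.5 cluster named epithelial-like (2.68%, but 0 with all libraries clustered together) was also led by Lum (8.47) and Postn (6.34), which are interstitial markers.

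In the newborn valve, P0 replicate 1 had an unnamed cluster of 30 cells, 3 endothelial markers raised, with Prox1, a transcription factor of lymphatic and valve endothelium, at 2.44 per 10000, Enpp2 at 4.57, Hbegf at 4.52, Cldn11 at 2.79 and Gja4 at 3.71. The endothelial-like cluster of that library had 0.333, 0.250, 0.444, 0 and 1.19, and the undivided endothelial-like cluster of replicate 2 had 1.02, 1.61, 2.53, 1.81 and 1.40. An unnamed cluster with interstitial markers, set apart from the interstitial-like one, appeared in all 3 valve libraries, with Aspn at 12.5 and 12.6 at P0 and 2.59 at E16.5, Tcf21 at 3.95, 2.52 and 1.89, and Dlk1 at 7.28, 7.17 and 19.1. The interstitial-like clusters had Aspn at 0.797, 1.20 and 0.179. At P0 this cluster also held Tnnt2 at 4.88 and 6.17, against 0.432 and 0.523. Capillary or coronary endothelial-like cells included a cycling group in P0 replicate 1, with cell cycle genes at 111.8 per 10000 against 36.4 in the other capillary cluster, and stood at 83.2 in replicate 2 and 42.3 at E16.5. An unnamed E16.5 cluster of 41 cells, led by the stress genes Thbs1, Ccl2 and Ddit3, had Sox9 at 2.52 and Postn at 17.7. Macrophage-like cells made up 3.56% and 6.82% at P0, and smooth muscle or pericyte-like cells 12.9% and cardiomyocyte-like cells 3.23% at E16.5. These shares depend on the clustering, as given above for macrophage-like cells. The smooth muscle or pericyte-like share ranged up to 25.8%, and was 0 with at least 1000 genes per cell or all libraries clustered together. Cardiomyocyte-like cells reached 8.12% at E16.5.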
